A study of Mus musculus with 4 samples.

How the data were processed

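Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complex 2, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse embryonic fibroblasts. Per the labels, the fibroblasts came from female fetuses at embryonic day 13.5 of strain C57BL6/J, the antibody was the mouse monoclonal CMA323, and an input library without antibody was made for each genotype. The series comprised 4 libraries: a ChIP and an input from Smchd1 +/+ cells (WT) and a ChIP and an input from Smchd1 MD1/MD1 cells (MD1). The series' design describes the latter as deficient for SmcHD1. There was 1 library of each kind, so no test between the genotypes was possible and no p-value is given.

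The authors deposited 1 table with 1 row per gene, giving a symbol, a position, a strand and 1 value for each genotype. Per the file headers the values are H3K27me3 enrichments in WT and MD1, and they lie on a log2 scale, as the deposited values run from -5.91 to 4.31 in WT and from -7.41 to 4.45 in MD1. The submitters' processing notes name the genome build mm9. The aligner, the counting of reads, the filters and the denominator of the enrichment are not given in the sources used here. In both columns nearly every deposited log2 value (99.99% in WT and 99.98% in MD1, at a relative tolerance of 1e-12) equalled 1 constant plus the log2 of a ratio of whole numbers no greater than 20000. The constants were 0.043 for WT and -0.032 for MD1. This is the form that a ChIP read count over an input read count with 1 scaling factor per genotype takes. Such ratios are known only in lowest terms, so the read counts behind them, and the depth of the libraries, remain unknown, and no counting interval is given. In lowest terms the median numerator and denominator were 79 and 135 in WT and 60 and 128 in MD1.

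The table listed 22691 genes, 952 of them on the X chromosome and 21739 on the 19 autosomes. Both genotypes had a value for 20606 genes, 770 on the X and 19836 on autosomes, and only these were compared. A further 1975 genes had no value in either genotype, 68 had one in WT alone and 42 in MD1 alone. None of the 1545 genes shorter than 1000 bp had a value, and 430 longer genes lacked both. A gene whose mark was lost to no reads at all in MD1 would drop out of a log ratio, and 4 X genes had a value in WT alone. As many X genes, 4, had a value in MD1 alone. Positions are given for mm9 with the first base counted as 1. The table's starts count from 0, since end minus start equalled the RefSeq gene length for 9510 of 21376 symbols found in a RefSeq table and end minus start plus 1 for 620. The intervals of 3405 compared genes, 101 on the X, overlap another listed gene, and ChIP reads carry no strand, so such genes can share reads.

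The difference D was the MD1 value minus the WT value, so that -1 is a 2-fold lower and 1 a 2-fold higher enrichment. The mean level of a gene was the mean of its log2 values in both genotypes. Before the data were examined, the 2-fold limit, 17 gene lists (6 X-linked and 11 autosomal), the rule for named genes and the other settings to be tried were fixed. The rule named, among genes with a mean level at or above the median of all genes, the 10 X genes with the lowest and the 10 with the highest D, and the 5 autosomal genes each way. From each list it named the up to 4 members with the largest absolute D, and it always named Smchd1 and Xist. Other genes given as examples were picked after their values were seen. Some genes that the rule names are not reported here. A list's median D was placed among 10000 random lists of the same size drawn from the same chromosome class and matched on mean level in 20 bins (seed 1). These percentiles describe this pair of libraries and are not p-values. Since the mean level itself holds the MD1 value, a list that lost the mark is matched to other genes that did, and percentiles matched on the WT value alone were added. Members of a list on the other chromosome class were left out. X genes were also summarised in windows of 2 Mb with at least 5 genes.

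The MD1 values were more widely spread than the WT values, with a slope of 1.25 for MD1 on WT over autosomal genes, so low genes were lower and the autosomal median of D was -0.27. A level-matched D was therefore added after the data were seen. It is D minus the median D of the 500 autosomal genes nearest in mean level within the same length quartile, and their spread served as the yardstick for single genes in place of replicates. Over autosomal genes the standard deviation (SD) of level-matched D was 0.86 in the shortest length quartile and 0.28 in the longest, so values of short genes are less certain. The other settings were pseudocounts of 0.01 and 1 on the linear ratio, a filter at the 25th percentile of mean level, centring on the autosomal median, leaving out duplicates, limits of 1.5-fold and 3-fold, means for medians, windows of 1 and 5 Mb, quartiles of the WT value and random runs of neighbouring genes. Genes overlapping no other gene, genes with a denominator of at least 20 in lowest terms in both genotypes, and matching on length were added. Where a value has no replicate, another setting was held to have moved it when it left the exact binomial 95% interval of the median (over genes), a bootstrap interval of 1000 draws for a difference of medians, or a factor of 1.5 for a count. A single named gene was held to have moved when it shifted by more than the SD of its level-matched autosomal genes.

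The steps were tested on simulated data in which 200 X genes were changed among 20606 genes of the MD1 and WT comparison. All 100 genes with a log2 change of -3 and 96 of 100 with a change of 2 were called by level-matched D, against 26 of 570 unchanged X genes (4.56%). Noise was drawn with the matched SD around the matched median. Each gene kept its real mean level for the matching, whereas in the data a change in MD1 moves that level. These calls were thus largely set in advance, and no change near the 2-fold limit was simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.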

Results

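H3K27me3 enrichment was compared per gene between female embryonic fibroblasts with and without SmcHD1, a noncanonical SMC-family chromatin protein concentrated on the inactive X chromosome. Female fibroblasts carry an active X, which mostly lacks H3K27me3, and an inactive X coated with it, so that an X-linked value averages both. The series' title names the question as the role of SmcHD1 in the epigenetic states by which X inactivation is maintained. The values were log2 enrichments for 770 X-linked and 19836 autosomal genes in WT (Smchd1 +/+) and MD1 (Smchd1 MD1/MD1) cells, with 1 ChIP library and 1 input library per genotype and therefore no replicate error. The depth of the libraries is unknown. Differences are given as MD1 minus WT on the log2 scale and are set against the autosomal genes of the same libraries.

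X-linked genes carried more H3K27me3 than autosomal genes in both genotypes, and the median X gene was not lower in MD1 cells. The median X-linked enrichment was 0.84 in WT (quartiles 0.29 and 1.27) and 1.40 in MD1 (quartiles 0.22 and 1.88). These medians stood at percentiles 81.7 and 89.6 of the autosomal genes of the same genotype. The autosomal median was -0.78 in WT and -0.90 in MD1. The median difference was 0.55 on the X and -0.27 on autosomes, an X-autosome gap of 0.82, and the median on each of the 19 autosomes was negative, whereas that of the X was positive. Relative to autosomal genes of like level and length the X median difference was 0.45. The mean X difference was 0.038, because the X genes split into a large group with higher and a smaller group with much lower enrichment. Across genes, which are not independent replicates, WT and MD1 values correlated with r = 0.95 on autosomes and r = 0.41 on the X.

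**Figure D1:**
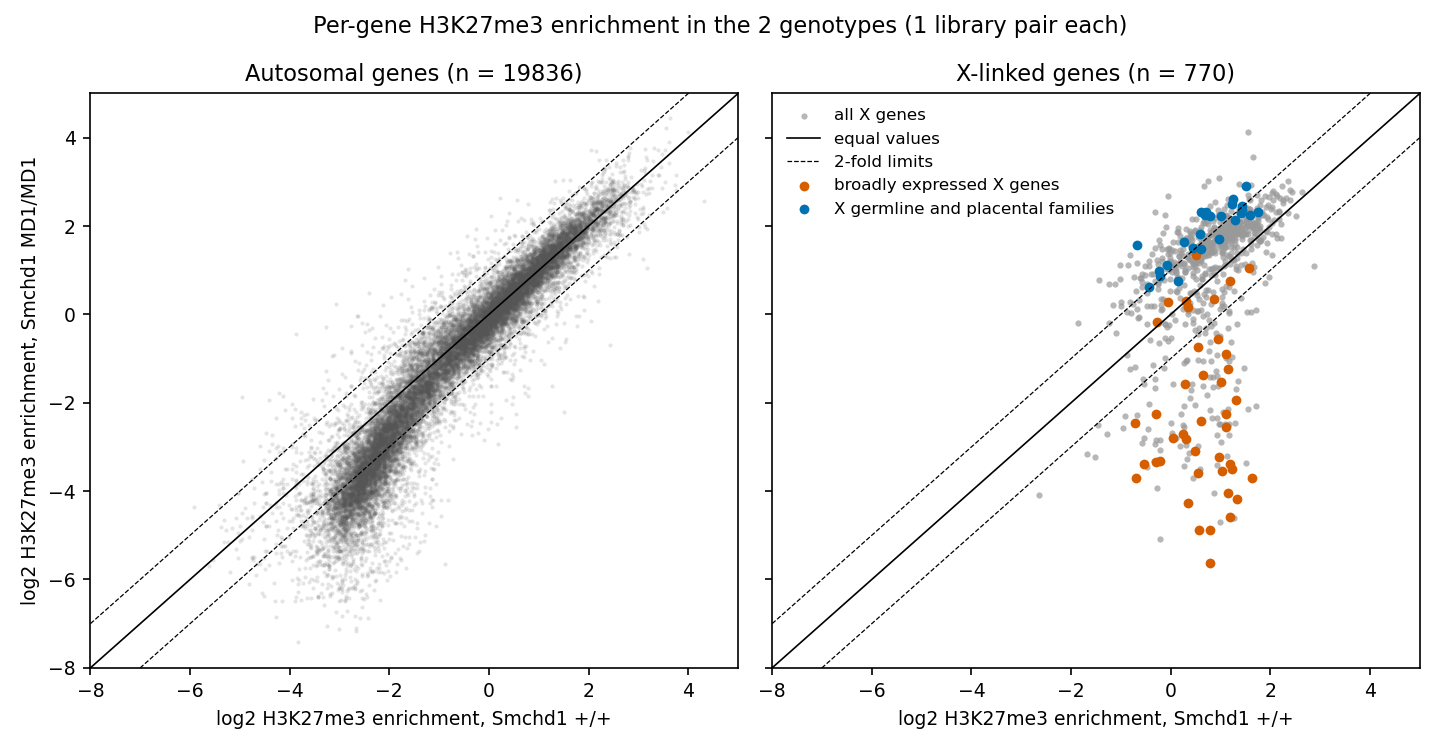
Each point is a gene, with its log2 H3K27me3 enrichment in WT cells on the x axis and in MD1 cells on the y axis, for autosomal genes (left) and X-linked genes (right). The solid line marks equal values and the dashed lines the 2-fold limits; the broadly expressed X genes (orange) have a median of -2.63 in MD1 cells, while the X germline and placental families (blue) lie at a median of 2.24.

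H3K27me3 was at least 2-fold lower in MD1 cells at 141 X genes (18.3%) and at least 2-fold higher at 170 (22.1%). The lower genes went from a median of 0.77 in WT, percentile 80.6 of autosomal genes, to -2.31 in MD1, percentile 33.6, a median difference of -2.55. The higher genes went from 0.32 to 1.68. On autosomes 4046 genes (20.4%) were at least 2-fold lower and 320 (1.61%) higher, and 691 lower ones had a mean level at or above the 25th percentile of all genes. Centred on the autosomal median, 128 of the X genes were lower and 288 higher, against 2638 and 638 autosomal genes. With a pseudocount of 1 on the linear ratio, 63 X genes were lower and 47 higher, against 31 and 35 autosomal genes, so the direction with more X genes turned. It turned also among 568 X genes with denominators of at least 20, of which 105 were lower and 96 higher. At a limit of 3-fold it turned as well, with 109 X genes lower and 39 higher. Relative to autosomal genes of like level and length, 134 X genes (17.4%) were lower and 145 (18.8%) higher, against 679 (3.42%) and 630 (3.18%) autosomal genes. In the longest length quartile, where values were least scattered, 25 of 204 X genes (12.3%) were lower and 22 (10.8%) higher by this measure, against 0.24% and 0.34% of autosomal genes.

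The lower X genes included most of a list of broadly expressed X genes, fixed from general knowledge of the genes since expression was not measured here. Of its 42 genes, 34 were at least 2-fold lower in MD1 and none was at least 2-fold higher, and the same number, 34, were lower relative to level-matched autosomal genes. The median went from 0.63 to -2.63, a difference of -3.03 (quartiles -4.49 and -1.76), or 8.15-fold. The 4 largest differences were at Emd, encoding the nuclear envelope protein emerin (-6.41), Nono, encoding an RNA-binding paraspeckle protein (-5.79), the ribosomal protein gene Rpl10 (-5.68) and the deubiquitinase gene Usp9x (-5.51). Usp9x (X, 12648624 to 12750453) went from 1.33 to -4.19 and Nono (X, 98624990 to 98643932) from 1.20 to -4.59, and none of their 500 level-matched autosomal genes had so low a difference. In lowest terms the MD1 ratios of Emd and Rpl10 were 1 to 48 and 1 to 29, so these values may rest on a single ChIP read, whereas those of Usp9x and Nono were 85 to 1516 and 12 to 283. Huwe1 (-5.19), Ogt (-4.72), Flna (-4.63), G6pdx (-4.13) and Hprt (-3.13) were also lower. The 8 members within the limits included Dkc1, at 0.50 in WT and 1.35 in MD1, Pdha1, at 0.34 and 0.17, and Pgrmc1, at 0.31 in both. The list's median difference lay at percentile 0.04 of random X lists matched on mean level and at percentile 0 when matched on the WT value.

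Among genes with a mean level at or above the median of all genes, the 10 lowest differences on the X ran from -3.78 to -3.27. They included those of Smc1a, encoding a cohesin subunit, the chromokinesin gene Kif4, the Mediator subunit gene Med12, Bcap31, encoding an endoplasmic reticulum membrane protein, the mitotic helicase gene Ercc6l, 5730405O15Rik, Atp6ap2, Armcx5 and Taz. Smc1a (X, 148450971 to 148496516) went from 1.72 in WT to -2.06 in MD1, against an SD of 0.28 among level-matched autosomal genes. Kif4 (X, 97821404 to 97922610) went from 1.29 to -2.46 with a matched SD of 0.30. Armcx5 is the gene of these 10 whose interval overlaps another gene and the one below which a matched autosomal gene, 1 of 500, also lay. The 10 genes were picked as the lowest, which favours such ranks.

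Genes known to escape X inactivation had, as a list, a lower median than the X in both genotypes. Of 15 escape genes, 10 were at least 2-fold lower and none at least 2-fold higher, and the median went from -0.47 to -1.82, a difference of -1.44 (quartiles -1.64 and -0.41). The 95% interval of that median over genes, -1.69 to 0.10, reached above 0, and 4 of the 15 differences were positive. Relative to level-matched autosomal genes 5 were lower and the median difference was -0.80. The histone demethylase genes Kdm5c and Kdm6a went from -1.53 to -3.22 and from -1.47 to -2.51, the RNA helicase gene Ddx3x from -1.68 to -3.17 and the translation factor gene Eif2s3x from -2.65 to -4.09. Relative to level-matched genes these 4 differed by -0.95, -0.46, -0.80 and -0.068, all within the limit. The positive differences were at Mid1 (0.62), Shroom4 (0.57), Xist (0.26) and Car5b (0.10). Larger differences were found at 1810030O07Rik (-3.64), Bgn (-2.56) and Utp14a (-2.28), which stood at 0.92, 0.74 and 0.65 in WT. The list was at percentile 0.26 of random X lists matched on the WT value, but at percentile 96.6 of those matched on the mean level, where its low level paired it with other X genes that were lower in MD1.

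In the X inactivation centre, the region that controls the choice and onset of inactivation, differences were small at most genes. Of 11 genes with values, 2 were at least 2-fold lower, Rlim, encoding an E3 ubiquitin ligase that activates Xist (from 1.36 to -1.51), and the noncoding RNA gene Ftx (from -0.31 to -1.67). Jpx differed by -0.92 and Nap1l2 by -0.49. Xist itself (X, 100655712 to 100678572), whose RNA coats the inactive X, stood at -0.47 in WT and -0.21 in MD1, a difference of 0.26 that 67 of 500 matched autosomal genes exceeded; its interval overlaps that of its antisense gene Tsix. The list median of -0.29 was at percentile 0.90 of random X lists matched on mean level and at percentile 16.4 of runs of neighbouring X genes. Of the X macrosatellite loci, Firre had a value, 0.40 in WT and 0.48 in MD1, a difference of 0.082, and the other gene asked for, 4933407K13Rik, had none in either genotype.

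H3K27me3 was higher in MD1 at X-linked genes restricted to the germline and placenta. All 25 members of these families with values had a positive difference, 17 of them at least 2-fold, out of 66 members listed. Of all X genes, 69.1% had a positive difference. Among the 25 were 12 Rhox genes, 7 of them at least 2-fold higher. Neighbouring X genes differed alike (below), so the 25 are not independent. The median went from 0.70 to 2.24, a difference of 1.20 (quartiles 0.89 and 1.37), at percentile 100 of random X lists matched on mean level and percentile 96.3 of runs of neighbouring X genes. The largest were Ssxb10 (2.24), the homeobox genes Rhox2h (1.72) and Rhox2g (1.62) and Magea6 (1.57). Their WT ratios in lowest terms were 11 to 18, 37 to 25, 30 to 19 and 14 to 9. Members of these families are near-identical in part, so how multiply mapping reads were counted could set their values. X-linked genes of neurons and muscle showed a smaller difference: 15 of 19 were positive, 1 at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.45, at percentile 13.51 of random X lists. The glutamate receptor gene Gria3 went from 0.25 to 1.49 and the dystrophin gene Dmd from 0.47 to 1.44, Fhl1 differed by 0.999, just within the limit, and Slc6a8, encoding a creatine transporter, went from 0.96 to -2.48.

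The 10 highest differences on the X, among genes with a mean level at or above the median of all genes, ran from 2.14 to 2.72. They belonged to Gm5124, Gm16390, Sowahd, Actrt1, 6330419J24Rik, Bex1, Ssxb10, Ubqln2, Cdr1 and Gm15008. Sowahd (X, 34588840 to 34590413) went from 1.55 to 4.12, the highest MD1 value of any named gene, and Bex1 (X, 132748511 to 132750052) from 0.66 to 2.90. At most 2 of 500 matched autosomal genes exceeded any of the 10, but these genes were picked as the highest, which favours such ranks. For the 5 highest autosomal genes, picked by the same rule, that number was at most 4 of 500 (Gm3434). The matched SDs of the 10 X genes were 0.37 to 0.77, and their ratios in lowest terms had WT denominators of 6 to 53. Short genes held more of the large positive differences, with 76 of 224 X genes in the shortest length quartile at least 2-fold higher against 29 of 204 in the longest.

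The lower genes were spread unevenly along the X. Of 47 windows of 2 Mb with at least 5 genes, 8 (17.0%) had a median difference below 0, and 25 of the 39 windows with a positive median still held a gene at least 2-fold lower. The window from 70 to 72 Mb had the lowest median, -2.24, and 30 of its 51 genes were at least 2-fold lower, among them Bcap31, Flna, Emd, Rpl10 and G6pdx. The window from 12 to 14 Mb, with Usp9x, had a median of -1.13 over 13 genes, and that from 98 to 100 Mb, with Nono, Taf1, Ogt and Rps4x, a median of -0.52 with 11 of 26 genes lower. The 5 windows richest in lower genes held 70 of the 141 among 175 genes with values, a share raised by picking them for that number. Of these windows, that from 34 to 36 Mb had 13 of 38 genes lower but a median of 0.61. In that from 6 to 8 Mb 9 of 47 genes were lower, near the share of 18.3% on the whole X. In the other direction, 6 windows had a median of 1 or more. In windows of 5 Mb the share with a median below 0 was 7.41%.

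**Figure D2:**
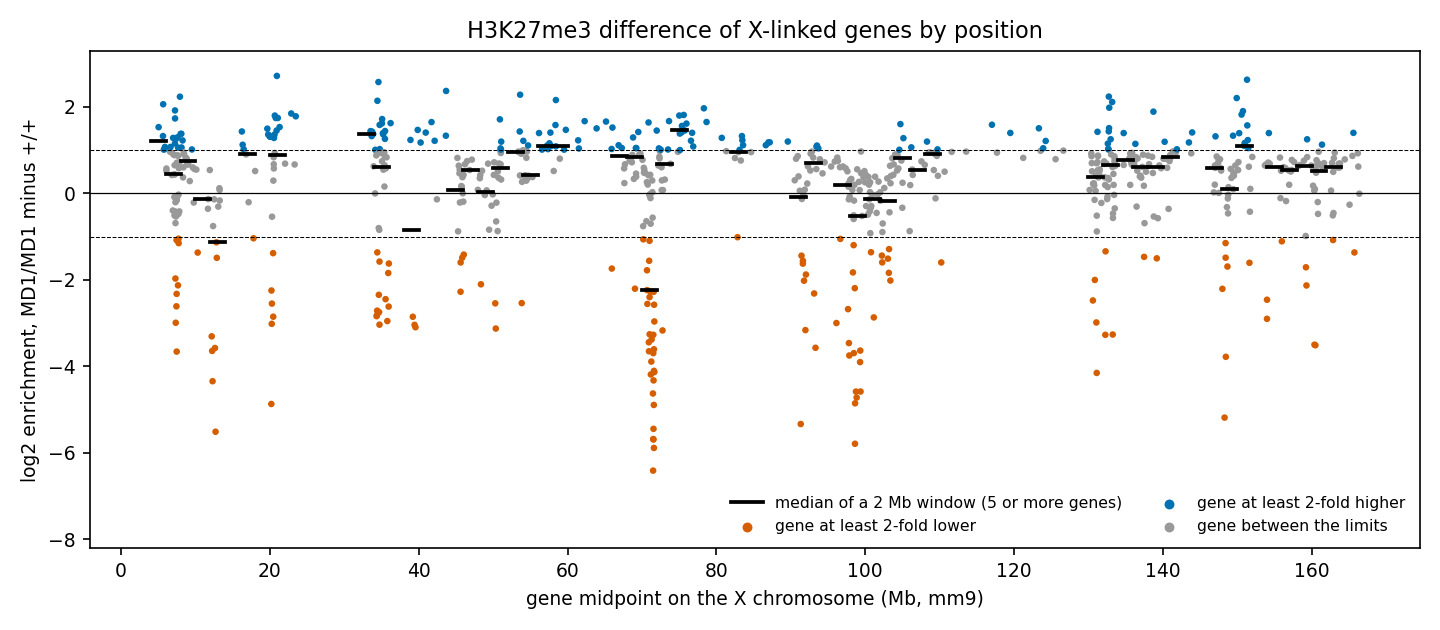
Each point is an X-linked gene, with its midpoint in Mb (mm9) on the x axis and its log2 H3K27me3 enrichment in MD1 minus WT on the y axis; black bars are medians of 2 Mb windows with at least 5 genes and dashed lines the 2-fold limits. Genes at least 2-fold lower (orange, 141 genes) form columns, the densest between 70 and 72 Mb with a window median of -2.24, amid genes with higher values.

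X genes were also split by level. By quartile of the mean level, the median difference was -1.84 in the lowest quartile, which held 125 of the 141 lower genes, and 0.72, 0.77 and 0.55 in the others. The mean level holds the MD1 value, so genes lower in MD1 fall into the lowest quartile by construction. By quartile of the WT value it was 0.87, 0.69, 0.56 and 0.37 from the lowest to the highest, and the lower genes numbered 44, 35, 43 and 19. Genes at least 2-fold lower in MD1 were thus found in each quartile of the WT value. Since D subtracts the WT value, scatter in that value alone favours a fall of D from the lowest to the highest quartile.

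On autosomes, the Hox genes, clustered regulators of body axis identity and Polycomb targets, were higher in MD1 as a list. Of 39, 15 were at least 2-fold higher and 1, Hoxd13 (-1.30), at least 2-fold lower, and the median went from 1.15 to 1.85, a difference of 0.74 (quartiles -0.0071 and 1.33) at percentile 100 of random autosomal lists. The largest were Hoxc6 (15, 102839993 to 102842312), from -0.27 to 1.93, Hoxb8 (11, 96143219 to 96146639), from -0.29 to 1.71, Hoxc5, from 0.41 to 2.30, and Hoxc8, from 0.37 to 2.11. Other developmental transcription factor genes stood among the most enriched autosomal genes in both genotypes, with medians of 2.24 in WT and 2.17 in MD1 and a median difference of -0.041 over 62 genes, which turned to 0.23 when centred on the autosomal median. Of these, 4 were at least 2-fold lower, among them Irx1 (-1.67) and Barhl2 (-1.04), and 1 was higher, Emx2 (1.18). That list was at percentile 0.27 of lists matched on mean level, but at percentile 10.3 when matched on the WT value.

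Imprinted and protocadherin clusters, which are known targets of SmcHD1, differed in both directions. Of 38 imprinted genes with values, 6 were at least 2-fold lower and 4 at least 2-fold higher. Their median difference of 0.058 was at percentile 99.3 of random lists and at 97.49 of runs of neighbouring genes. Relative to level-matched genes 3 were lower and 3 higher. Peg12 (7, 69606757 to 69609396) had the largest difference of any imprinted gene, from -0.87 to -5.65, with an MD1 ratio of 1 to 49 in lowest terms, and relative to level-matched genes its difference was -3.54, with 1 of 500 as low. Its neighbours on chromosome 7, Mkrn3 and Ndn, differed by -1.21 and -1.06, or by -1.06 and -0.77 relative to level-matched genes, whereas Magel2 between them went from 0.64 to 2.18. H19 went from -0.40 to 1.36, Mest from -1.04 to 0.14 and Cdkn1c from 1.08 to 2.12. Cd81 went from -2.24 to -4.83, a difference of -2.59 that became -1.09 relative to level-matched genes, 29 of 500 of which were as low. Ube3a differed by -1.54 and Osbpl5 by -1.01. Among 59 clustered protocadherin genes on chromosome 18, which encode neuronal cell adhesion proteins, 11 were at least 2-fold higher and 6 lower. The 11 higher ones were all of the 22 Pcdhb genes, led by Pcdhb2 (-2.42 to 0.49), Pcdhb12 (-1.31 to 0.83), Pcdhb3 (-0.62 to 1.28) and Pcdhb1 (-0.57 to 1.11), while the 15 Pcdha genes had a median of -0.86 and the 22 Pcdhg genes one of -0.41, which turned to 0.14 relative to level-matched genes. In lowest terms the WT ratio of Pcdhb2 was 2 to 11, with a matched SD of 0.92, so its difference may rest on few ChIP reads. All 59 intervals overlap another listed gene, so the Pcdha values, and likewise the Pcdhg values, are not independent of each other. The 22 Pcdhb genes can share reads too. The list's median of -0.38 turned to 0.15 relative to level-matched genes.

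Genes active in fibroblasts had little mark in either genotype. Of 23 fibroblast genes, with medians of -2.73 in WT and -3.58 in MD1, 9 were at least 2-fold lower, led by Fn1 (-2.19), Tagln (-2.16), Vim (-2.10) and Prrx1 (-1.93), but none was lower and 3 were higher relative to level-matched genes, where the list's median turned from -0.64 to 0.36. The list was at percentile 96.4 of random lists matched on mean level. Of 20 autosomal housekeeping genes, with medians of -2.90 and -4.40, 12 were at least 2-fold lower and 1, Eef1a1 (1.01), higher, and 3 were lower and 3 higher relative to level-matched genes, with a median of -1.43 that became -0.069. This list was at percentile 52.9 of random lists matched on mean level, but at 1.67 when matched on the WT value and at 0.11 of runs of neighbouring genes. The lowest were Rplp0 (-4.07), B2m (-3.73), Tubb5 (-3.40) and Hnrnpk (-2.35), which became -2.60, -2.30, -1.77 and -0.68 relative to level-matched genes. Their MD1 numerators in lowest terms were 1, 2, 1 and 5. Markers of other cell types had medians near 0. The median difference was -0.0014 over 9 blood and endothelial genes, 0.071 over 9 epithelial genes and -0.084 over 12 muscle and neuron genes, and Cd68 (-1.57) alone of these passed the limit, though not relative to level-matched genes (-0.34). Of 11 autosomal germline genes, with a median of -0.095, Sycp3 (-1.16) was at least 2-fold lower, but was at -0.56 relative to level-matched genes. Of 245 olfactory receptor genes with values, 36 were lower and 15 higher, with a median of -0.13 and the largest differences at Olfr968 (-3.12), Olfr294 (-2.88), Olfr619 (-2.76) and Olfr1107 (-2.65), all short genes. Centring on the autosomal median adds 0.27 to every difference, and with it the medians of these 5 lists were all positive.

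Among autosomal genes with a mean level at or above the median of all genes, the lowest differences were at the insulin gene Ins1 (-3.70), Olfr968, Olfr294, Olfr1042 (-2.62) and Lce1f (-2.49), and the highest at Dusp28 (2.64), Ch25h (2.48), Tmem158 (2.42), Gm3434 (2.22) and Chchd10 (2.21). All 10 are short, with matched SDs of 0.52 to 0.82, and their denominators in lowest terms ran from 2 to 25. At Smchd1 (17, 71693834 to 71824683) enrichment was -2.44 in WT and -3.47 in MD1, a difference of -1.04 that became 0.027 relative to level-matched genes. A ChIP value does not show whether the mutant allele makes protein, so it does not check the genotype labels.

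**Figure D3:**
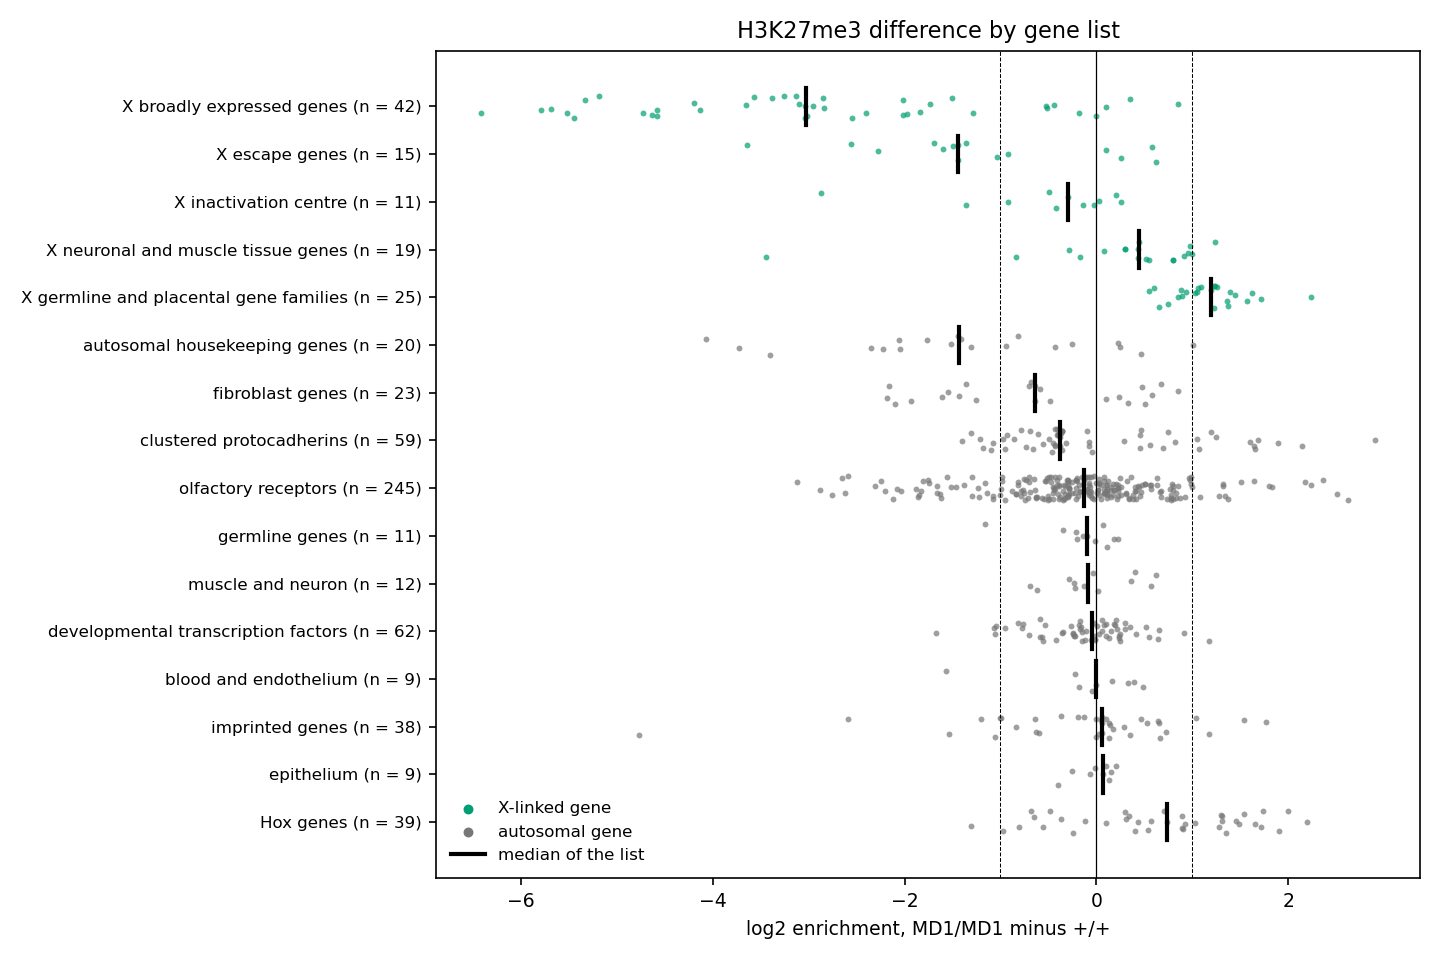
Each point is a gene, placed by its log2 H3K27me3 enrichment in MD1 minus WT on the x axis, in the list named on the y axis with its number of genes (blood and endothelium, epithelium, and muscle and neuron are markers of other cell types). Black bars are list medians, from -3.03 for broadly expressed X genes and 1.20 for X germline and placental families to -1.43 for autosomal housekeeping genes and 0.74 for Hox genes; dashed lines are the 2-fold limits.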

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

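No paired analysis was possible, and no library could be left out, because each genotype had 1 ChIP and 1 input library. The table gives 1 enrichment per genotype and no separate ChIP and input values, so the ChIP-alone alternative was not run, and centring sets the autosomal median to zero by construction. The level-matched, overlap, denominator and length settings were chosen after seeing the data. No duplicates were found among compared genes. A pseudocount of 0.01 kept all named genes, and the 24 of 30 summaries it was run on, within their limits. A pseudocount of 1 moved 66 of 94 values of named genes, such as Usp9x to -1.73, Smc1a to -1.79 and Emd to -1.42. Level matching moved 14 and reversed 1 (Smchd1, below), and centring moved 8. With a pseudocount of 1, which compresses low values, the X median was 0.39, the autosomal median -0.082 and their gap 0.47. The X counts were then 63 lower and 47 higher and the autosomal counts 31 and 35. The gap between level quartiles, 2.39 as reported, was 1.10, and list medians were -1.01 (X broadly expressed), 0.74 (X germline) and -0.078 (autosomal housekeeping). Centring gave an X median of 0.82, 288 higher X genes, and 2638 lower and 638 higher autosomal genes. It also gave list medians of 1.47 (X germline), 0.33 (imprinted), 0.23 (developmental factors) and 0.34 (epithelium), moved the Firre difference to 0.35 and turned the olfactory receptors from -0.13 to 0.15. Level matching gave an X median of 0.45, an autosomal median of -0.0018 and a gap of 0.45, with 679 lower and 630 higher autosomal genes. It turned the protocadherin median to 0.15 and Smchd1 to 0.027, and gave 0.18 (imprinted), 0.36 (fibroblast) and -0.069 (autosomal housekeeping). The 25th percentile filter gave an autosomal median of -0.10, a gap of 0.66, 691 lower autosomal genes and autosomal levels of -0.067 (WT) and -0.15 (MD1). It left 1 autosomal housekeeping gene, at 0.25, and 8 fibroblast genes with a median of 0.49, so both signs turned by the choice of genes. Means gave 0.038 on the X, -0.42 on autosomes and a gap of 0.46. Genes overlapping no other gave an autosomal median of -0.26. A denominator of at least 20 gave an autosomal median of -0.29, with 105 lower and 96 higher X genes of 568 and 124 higher autosomal genes. At 1.5-fold, 367 X genes were higher and 6822 autosomal genes lower and 1001 higher. At 3-fold the numbers were 39, 1509 and 84. In 5 Mb windows 7.41% had a median below 0. Quartiles of the WT value reversed the gap between level quartiles to -0.50. The mean level holds the MD1 value and D subtracts the WT value, so neither gap is free of its sorting. The cause of other moves was not tested. The count of lower X genes stayed within a factor of 1.5 in every setting but the pseudocount of 1. Beyond the percentiles given with the lists, runs of neighbouring genes put protocadherins at percentile 22.9 and developmental factors at 94.6. Unknown depth limits single short genes most.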

Other observations

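All groups and tests in this part were chosen after the values were seen, except the test on limb genes, whose prediction was written first. Values of some further gene families, picked for their values, follow; 69.1% of all X genes and 31.0% of all autosomal genes had positive differences. On the X, 9 of 10 Bex and Tceal genes, small proteins of the brain-expressed X-linked family and its relatives, had positive differences, with a median of 1.02 and the largest values at Bex1 (2.24), Tceal3 (2.11) and Ngfrap1 (1.98), while Tceal6 was at -0.22. Of 6 Armcx genes, 5 were positive, such as Armcx4 (1.42), whereas Armcx5 was at -3.27. On autosomes, all 6 compared members of the Dlk1 and Meg3 imprinted cluster had positive differences (median 0.68), led by 6430411K18Rik (2.08) and Rtl1 (1.34). The intervals of 2 of these 6 genes overlap another listed gene, so these can share reads. Of 12 genes of the placental cathepsin cluster on chromosome 13, 11 were positive (median 0.81), with Cts8 at 1.498 and Cts3 at 1.39. The 6 chemokine genes around Ccl2 were positive (median 0.72), with Ccl12 at 1.62 and Ccl7 at 1.33. The natural killer receptor family Klra had 15 of 18 positive differences and the vomeronasal receptor family Vmn2r 63 of 92, of which Vmn2r121 (0.82) lies on the X. The intervals of 15 of the 18 Klra genes overlap another listed gene, so these genes can share reads, and Klra6 and Klra19 had the same values. In the family Vmn1r, 9 of 28 genes were at least 2-fold higher and 4 lower. Of 58 olfactory receptor genes on chromosome 2, 40 had negative differences, near the share of all autosomal genes (13686 of 19836). At least 2-fold lower were 15 of the 58, against 22.2% of autosomal genes in the shortest length quartile and 20.4% of all autosomal genes. No biological explanation was tested for them.

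At 141 X genes the mark was at least 2-fold lower. MD1 values were more widely spread over autosomal genes (slope 1.25). A lower background in the MD1 ChIP library, which was not measured, could spread them so. Of the 141 genes, 134 (95.04%) were at least 2-fold lower relative to autosomal genes of like level and length too. These 141 genes were picked for low differences, and the mean level holds the MD1 value. This share thus cannot exclude a background shift that acts by level. Without such picking, 17.4% of the 770 X genes were lower by this measure, against 3.42% of autosomal genes. Few reads in short genes cannot be the whole cause, since 12.3% of X genes in the longest length quartile were lower (exact 95% interval 8.09% to 17.6%, over genes) against 0.24% of autosomal genes. Loss of the inactive X from the MD1 cells would take the mark from silent X genes too, yet the X neuronal and muscle list had a median level-matched difference of 0.42 (interval 0.096 to 0.80). That list was fixed from general knowledge, and whether its genes were silent in these cells was not measured. Over all 770 X genes the median level-matched difference was 0.45. That the mark is lost where promoters can be active in fibroblasts remains a hypothesis, as does a difference between the preparations: the share of lower genes was 75.7 percentage points higher in the broadly expressed X list than in the tissue list, but these counts prompted the hypothesis and do not test it, and expression was not measured here.

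Neighbouring X genes differed alike. Over 622 adjacent pairs of genes that overlap no other gene the correlation of differences was 0.59 across genes, against 0.079 as the upper limit of the central 95% of 10000 shuffles, so shared reads between overlapping genes are not the whole cause. Without the window from 70 to 72 Mb the correlation was 0.51 over 580 pairs, so it does not rest on that region alone. Clustering of broadly expressed genes and domains of regulation on the inactive X both remain candidate explanations and were not separated.

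Hox genes had differences in both directions, and whether these differ by cluster or by position was not tested. Of 19 HoxB and HoxC genes 18 had positive differences, 13 of them at least 2-fold, and the distal Hoxc10 (1.31) and Hoxc11 (0.44) were among the positive ones; medians were 0.82 for HoxA paralogs 1 to 9 (2 of 8 at least 2-fold higher) and 0.50 for HoxD paralogs 1 to 8 (none of 4, with Hoxd1 at -0.24), but -0.56 for HoxA paralogs 10 to 13 (none of 3 at least 2-fold lower) and -0.81 for HoxD paralogs 9 to 13 (1 of 5). Relative to level-matched genes the HoxB and HoxC median was 1.32 (interval 0.32 to 1.61). These genes were grouped after their values were seen, so this cannot exclude a background shift that acts by level. Fibroblast preparations that differ in axial or limb origin could give such a pattern, and limb genes would then lose the mark with the distal Hox genes. Of 9 limb genes 7 were below 0 relative to level-matched genes, among them Msx2 (-1.19), Lhx9 (-1.19), Hand2 (-0.68) and Lhx2 (-0.49), but the interval of their median of -0.14 ran from -1.19 to 0.31, so this origin and an effect of the genotype cannot be told apart.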
